A study of Mus musculus with 12 samples.

How the data were processed

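Total RNA of 12 mouse cell samples was measured on 1-colour Affymetrix gene arrays, after isolation on silica columns and preparation of biotinylated cDNA per the labels' protocols. The deposited table held 1 column per array and 35557 probe sets. The values are log2 signals that the authors made by RMA, which corrects background, equalises the distributions of the arrays and summarises probes by median polish, in Affymetrix Expression Console 1.3.1, per the submitters' processing notes. The log base is not written in the table and was taken from the RMA output and the range of the values (1.8747 to 13.8686). Array medians ran from 6.0935 to 6.2575. The genome build behind the probe design is not given in the sources used here. Arrays give no read depth, so their number limits the precision.

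The platform annotation listed 23410 of the probe sets, of which 21789 had 1 gene symbol and 1621 had several; 12147 probe sets were not listed. Probe sets with 1 symbol were used, and for 999 genes with more than 1 probe set the one with the highest mean signal was kept, which left 19938 genes. Entrez identifiers of 21698 probe sets matched a mouse gene table, used for names and chromosomes alone, and 0 symbols were updated. Probe sets with several genes or no listed gene were tested separately with the same model.

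Groups followed the labels: iPSC day 0, spontaneous day 4, cardiac day 4 and sorted CPC day 4, with 3 arrays each. An abbreviation for the cardiac condition in the labels was not expanded there and is not interpreted. All 12 arrays entered 1 linear model in limma 3.58.1 (R 4.3.3) with a mean per group, and 6 contrasts were tested with moderated statistics and an intensity trend of the prior variance (8 residual and 5.01 prior degrees of freedom). P-values were two-sided and adjusted by the Benjamini-Hochberg method over 19938 genes. A gene was called at an adjusted p under 0.05 with an absolute log2 fold change of at least 1. A moderated F test covered the 4 groups, and genes called higher in the sorted group than in each other group were counted. SDs are between the arrays of a group and SEs are those of the moderated contrast.

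Gene lists, 44 in number, covered pluripotency, germ layers and their derivatives, extraembryonic tissues, lysophospholipid signalling, developmental pathways, metabolism, cell cycle, stress and other cell types. Each list was tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the lists within a comparison. Camera compares a list with all other genes, and fry asks whether its members move 1 way on balance. Members were also counted after adjustment over the list alone. The overlap of calls was set beside the product expected of independent lists, and the correlation and covariance of the differences beside 50 simulations of unchanged groups against the same day 0 arrays.

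The groups, tests, thresholds, lists and rule for named genes were chosen before the data were examined. The rule named Lpar4, Kdr and Pdgfra; per comparison the 6 called genes with the largest rise and the 6 with the largest fall whose arrays did not overlap, without predicted loci, clones, small RNA and olfactory or vomeronasal receptor genes; per described list up to 4 called members with the largest change and up to 2 uncalled members with the highest mean; and up to 12 genes highest in the sorted group, of which there were 0. Lists were described if they passed camera or had many called members, and 5 lists were always described. Of the genes so chosen, the text names those whose calls it needs, with preference for calls that held with any 1 array left out.

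The model was tested on simulated data in which 200 of 19938 genes were changed. A log2 change of 1 was recovered in 46.9%, 37% and 46.4% of genes in the comparisons of spontaneous, cardiac and sorted cells with day 0, and in 47.5%, 43.6% and 39.5% for cardiac against spontaneous, sorted against cardiac and sorted against spontaneous. At 1.5 the recovery was 93.9%, 88.6%, 93.6%, 86.5%, 92.5% and 88.5% in this order, at 2 it was 98%, 100%, 98.1%, 98%, 98.2% and 98.6%, and at 3 it was 97.2% in the first and 100% in the others. False calls numbered 0, 0, 9, 1, 8 and 4, and 0 had the wrong direction. The noise was drawn independently for each gene, so arrays that deviate jointly over many genes were not simulated. The recovery therefore does not show that large differences between day 4 groups were absent.

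The alternatives were the replicate number as a block, a prior variance without trend or with robust estimation, array weights, a filter on dim genes, the mean of a gene's probe sets, centring on array medians, a repeated quantile normalization, cyclic loess, a fit of only the 6 arrays compared, no minimum fold change, a test against a log2 fold change of 1 (treat), and each array left out. Added after seeing the data were the fits without the libraries labelled sorted CPC replicates 2 and 3, the alternatives of the overlap, and the list tests with each array left out. Tables were prepared in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.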

Results

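The data are 12 Affymetrix gene arrays of mouse cells, 3 in each of 4 groups. The day 0 group held undifferentiated induced pluripotent stem cells (iPSCs), which are reprogrammed cells able to form all embryonic germ layers. The other 3 groups were taken at day 4 of differentiation: spontaneously differentiating cells, cells of an optimized cardiac differentiation, and cardiac progenitor cells (CPCs) sorted by flow cytometry for FLK1 and PDGFRα on their surface. FLK1 is the product of Kdr, a receptor for vascular endothelial growth factor, and PDGFRα is the product of Pdgfra, a receptor for platelet-derived growth factors. The series title names Lpar4, which encodes a G protein-coupled receptor for lysophosphatidic acid, so the comparisons ask how Lpar4 and the other genes differed between undifferentiated cells, both kinds of day 4 culture and sorted progenitors. Values are log2 RMA signals, given as mean ± SD over the 3 arrays of a group, and the number of arrays limits the precision of each. No background level was measured here, so signals around or below the array medians are not shown to exceed background. The mean day 0 signals of Kdr, Lpar4, Mixl1, Fgf5, Nrp1, Tbx20, Ttr, Apob, Bmp5, Spink1, Rab25 and Neurod1, among others, lay below these medians. Fold changes against them may be understated. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Within groups the lowest pairwise correlation across genes was 0.989 at day 0, 0.9922 in spontaneous cells, 0.973 in cardiac cultures and 0.9656 in the sorted group. The number of genes with an SD over 1 was 7, 14, 115 and 230 in the same order.

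The protein products of Kdr and Pdgfra defined the sorting gate, and the RNA of both genes served here as a check of the labels. Surface protein was not measured by the arrays, so low RNA does not show that sorted cells lacked it. At day 0, Kdr measured 5.5, 5.54 and 5.78 in replicates 1, 2 and 3. In spontaneous cells it measured 9.83, 10.71 and 10.27, and in cardiac cultures 5.42, 10.81 and 9.01. The library labelled sorted CPC replicate 1 had a Kdr value of 10.23, whereas the libraries labelled sorted CPC replicates 2 and 3 had 6.25 and 6.03, close to day 0. Pdgfra gave the same division, with 11.13 in the first and 8.47 and 8.29 in the other sorted libraries, against 8.75 to 9.14 at day 0. Cardiac replicate 1 was likewise near day 0 in Kdr. Kdr was 4.66 ± 1.17 (SE) higher in spontaneous cells than at day 0 (25.4-fold, adjusted p = 0.0246). That call was lost without any 1 of the 6 arrays (adjusted p = 0.0544 to 0.094). The SE pooled all groups (SD 0.15 at day 0, 0.44 spontaneous, 2.74 cardiac, 2.36 sorted), and all spontaneous arrays exceeded day 0. The Kdr difference from day 0 was 2.80 in cardiac cultures (adjusted p = 0.182) and 1.90 in the libraries labelled sorted (adjusted p = 0.427). The cardiac difference passed with cardiac replicate 1 left out (4.30, adjusted p = 0.0169), but that array stood apart by its Kdr value itself, so this is no separate test of Kdr. Pdgfra did not pass in any of these comparisons, with differences of 1.12, 0.86 and 0.40 in the 3 day 4 groups (adjusted p = 0.239, 0.37 and 0.766).

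Lpar4 rose in every day 4 group, and all 9 day 4 arrays lay above all 3 day 0 arrays. From 5.94 ± 0.53 at day 0 it reached 8.75 ± 0.05 in spontaneous cells, a log2 difference of 2.82 ± 0.42 (SE, 7.04-fold, adjusted p = 0.00184). In cardiac cultures it reached 8.37 ± 0.95 (2.44 ± 0.42 SE, 5.41-fold, adjusted p = 0.00534). In the libraries labelled sorted it reached 8.52 ± 0.65 (2.58 ± 0.42 SE, 5.99-fold, adjusted p = 0.00392). Each of these calls held with any 1 array left out. In the libraries labelled sorted CPC replicates 1, 2 and 3 Lpar4 measured 8.61, 9.12 and 7.83, a wider spread than in spontaneous cells. Between day 4 groups no Lpar4 difference passed the test: cardiac cultures differed from spontaneous cells by -0.38 (adjusted p = 0.999), sorted libraries from cardiac cultures by 0.15 (adjusted p = 0.865) and sorted libraries from spontaneous cells by -0.23 (adjusted p = 0.803), each with an SE of 0.42. Without cardiac replicate 1 the first 2 of these changed sign, to 0.15 and -0.38. The last 2 were 0.24 and -0.14 without sorted CPC replicates 2 and 3. The list of 11 lysophospholipid receptors did not pass camera in these comparisons either (adjusted p = 0.0544, 0.944 and 0.205), except without spontaneous replicate 3 between cardiac and spontaneous cells (0.0159). Its median and mean between sorted and cardiac libraries were 0.14 and 0.03, while the test direction was down. Ranked by the smallest of its 3 differences between the sorted group and the other groups, Lpar4 stood at 13768 of 19938 genes.

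**Figure D1:**
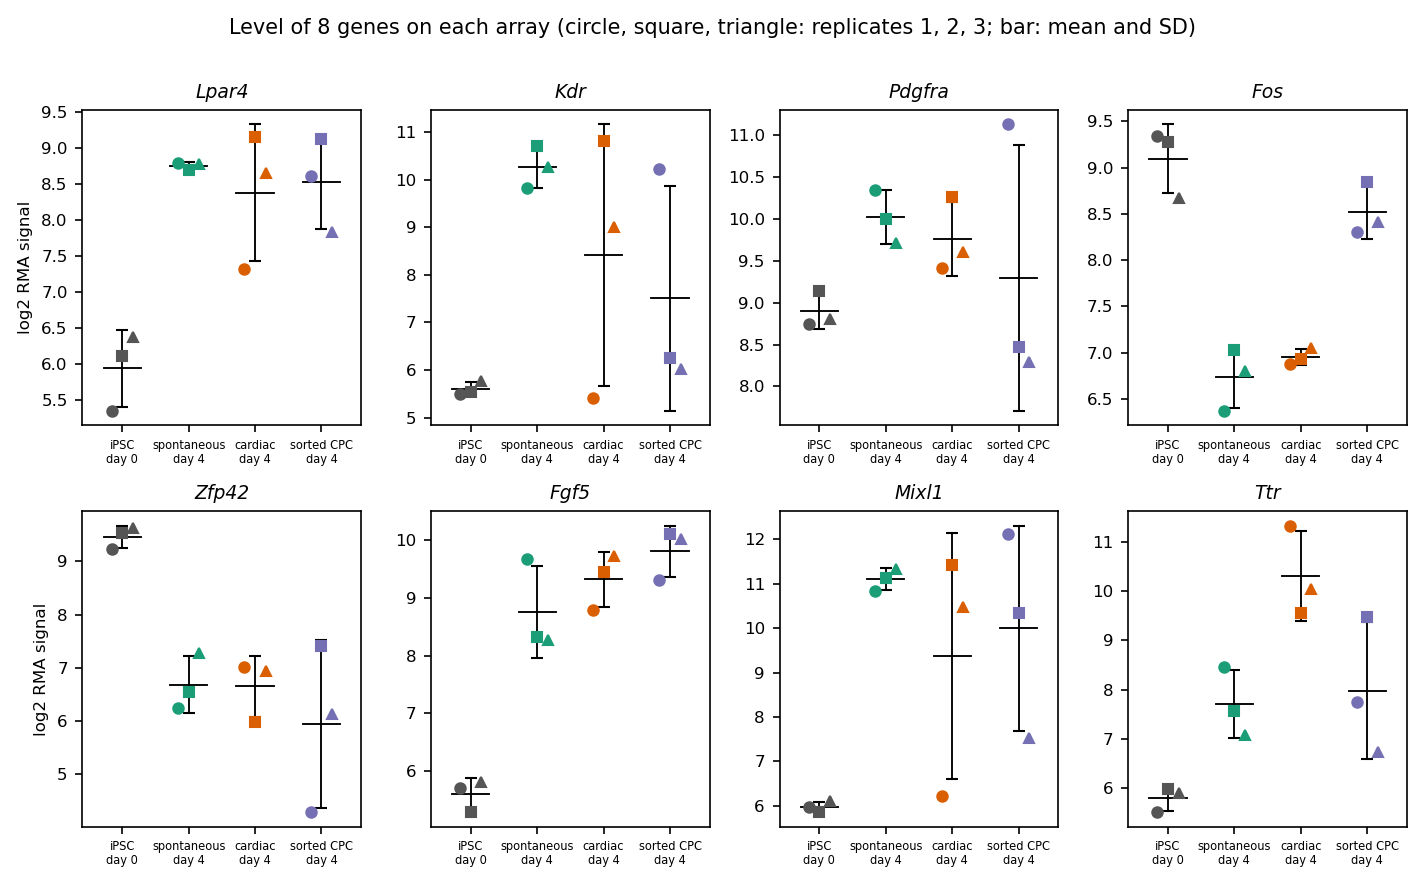
Log2 RMA signal of 8 genes on each of the 12 arrays, by group; circles, squares and triangles are replicates 1, 2 and 3, and bars give the group mean and SD. Lpar4 lay between 7.31 and 9.15 on all day 4 arrays and at or below 6.37 at day 0, while Kdr was 6.25 and 6.03 in the libraries labelled sorted CPC replicates 2 and 3.

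Spontaneous differentiation was compared with day 0 to see what 4 days without cardiac conditions changed. Eomes, a T-box factor of the primitive streak and mesendoderm, rose from 6.45 ± 0.46 to 10.74 ± 0.14 (19.5-fold, log2 difference 4.29 ± 0.66 SE, adjusted p = 0.00222). Cyp26a1, which degrades retinoic acid, rose 17-fold (4.09 ± 0.50 SE, adjusted p = 0.00069), and Has2, a hyaluronan synthase, rose 16.6-fold (4.05 ± 0.49 SE, adjusted p = 0.000683). Fgf5, a marker of postimplantation epiblast, rose 8.87-fold (3.15 ± 0.36 SE, adjusted p = 0.000517). Zfp42 (Rex1), a marker of naive pluripotency, fell from 9.46 ± 0.21 to 6.69 ± 0.53 (adjusted p = 0.0103), and Tcl1, a coactivator of Akt signalling in stem cells, fell by 2.91 (adjusted p = 0.000683). The largest difference was that of Mixl1, a homeobox gene of the streak, at 11.1 ± 0.25 against 5.98 ± 0.12 (34.9-fold, adjusted p = 0.0154). The Mixl1 call was lost without iPSC replicate 1 or 2 or spontaneous replicate 2 or 3 (adjusted p = 0.0544 to 0.0593). The Mixl1 SE pooled a cardiac SD of 2.77.

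Several gene lists fixed before the data were examined rose in spontaneous cells. Of 19 genes of primitive streak and nascent mesoderm, 5 rose and 0 fell (9 and 0 adjusted over the list alone), with a median log2 difference of 1.49 and a camera adjusted p = 1.14e-05. The adjusted p = 0.391 with an estimated correlation. Besides Eomes, Fgf8, a growth factor of the streak, rose by 1.77 (adjusted p = 0.0113). The count was 2 without iPSC replicate 1, iPSC replicate 2 or spontaneous replicate 2, and 3 without spontaneous replicate 3. Of 19 genes of lateral plate and cardiogenic mesoderm, 8 rose and 0 fell (also 8 and 0 adjusted over the list alone; median 1.12, adjusted p = 3.61e-06, and adjusted p = 0.391 with an estimated correlation). Among them Tbx20, a T-box factor needed for heart development, rose 11.4-fold (3.52 ± 0.53 SE, adjusted p = 0.00193) from a dim 5.17 at day 0, so that the fold may be understated. This count was 2 without spontaneous replicate 2, 3 without spontaneous replicate 3, 4 without iPSC replicate 1 or 2, and 5 without iPSC replicate 3. Of 22 cardiac progenitor transcription factors and related genes, 6 rose and 0 fell (6 and 0 adjusted over the list alone; median 0.50, adjusted p = 0.000856, and adjusted p = 0.424 with an estimated correlation); Gata6, a zinc finger factor of heart and endoderm, differed by 0.46 (adjusted p = 0.409). The count was 3 without iPSC replicate 2 or 3 or spontaneous replicate 2 or 3.

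Lists of other cell types moved as well in spontaneous cells. Of 15 definitive endoderm genes, 3 rose and 0 fell (6 and 0 adjusted over the list alone; median 0.37, adjusted p = 0.000895, and adjusted p = 0.292 with an estimated correlation). The count was 1 without iPSC replicate 1, spontaneous replicate 1 or spontaneous replicate 2. Of 24 surface ectoderm and epithelium genes, 5 rose and 0 fell (also 5 and 0 adjusted over the list alone; median 0.06, mean 0.46, adjusted p = 0.034, and adjusted p = 0.729 with an estimated correlation). The keratin genes Krt18 and Krt8 rose (2.54 and 2.38, adjusted p = 0.00934 and 0.00166). The epithelial count was 3 without iPSC replicate 1 or 2 or spontaneous replicate 1, 2 or 3. The call of the list was lost without iPSC replicate 2 (0.0728) or spontaneous replicate 1 (0.0642). Of 14 trophectoderm genes, 4 rose and 0 fell (also 4 and 0 adjusted over the list alone; median 0.03, mean 0.67, adjusted p = 0.04, and adjusted p = 0.391 with an estimated correlation). The homeobox gene Cdx2 rose by 1.27 (adjusted p = 0.00578). The trophectoderm count was 2 without iPSC replicate 1 or 2 or spontaneous replicate 2 or 3. The call of the list was lost without iPSC replicate 3 (0.0781). Of 18 formative and primed epiblast genes, 6 rose and 1 fell (7 and 1 adjusted over the list alone; median 0.61, adjusted p = 0.0294, and adjusted p = 0.391 with an estimated correlation). The epiblast count was 2 higher and 1 lower without iPSC replicate 1 or spontaneous replicate 2, and 3 higher and 1 lower without iPSC replicate 2 or spontaneous replicate 1 or 3. The call of the list was lost without iPSC replicate 1 (0.0567) or spontaneous replicate 1 (0.0913). Of 24 neuroectoderm genes, 2 rose and 3 fell (2 higher and 4 lower adjusted over the list alone; median -0.13, adjusted p = 0.0487, and adjusted p = 0.735 with an estimated correlation). The neuronal factor gene Neurod1 fell (-1.51, adjusted p = 0.00102). The neuroectoderm counts were 1 and 3, 1 and 1, and 0 and 3 without iPSC replicates 1, 2 and 3. They were 0 and 3, 0 and 2, and 1 and 3 without spontaneous replicates 1, 2 and 3. The call of this list was lost without iPSC replicate 1 (0.0516), iPSC replicate 3 (0.0814), spontaneous replicate 1 (0.0642) or spontaneous replicate 3 (0.0748).

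Some signalling lists and the imprinted genes also passed camera upward in spontaneous cells, while the FGF, NOTCH and retinoic acid lists did not pass (adjusted p = 0.957, 0.554 and 0.944). In the WNT pathway list of 30 genes, 7 rose and 0 fell (9 and 0 adjusted over the list alone; median 0.59, adjusted p = 4.51e-06, and adjusted p = 0.324 with an estimated correlation), among them the secreted WNT inhibitor Dkk1 (2.03, adjusted p = 0.00707). The number of WNT genes was 3 without iPSC replicate 1, 2 without iPSC replicate 2 or spontaneous replicate 3, and 1 without spontaneous replicate 2. In the BMP and TGF-beta list of 31 genes, 9 rose and 0 fell (11 and 0 adjusted over the list alone; median 0.41, adjusted p = 0.00757, and adjusted p = 0.499 with an estimated correlation). The ligand Bmp5 rose by 2.68 (adjusted p = 0.00681), whereas the receptor gene Bmpr1a differed by 0.73, under the minimum difference (adjusted p = 0.00671). Without iPSC replicate 2 the BMP count was 5, without spontaneous replicate 2 it was 2, and without spontaneous replicate 3 it was 4. In the list of vasculogenic and migration ligands and receptors, 7 of 27 rose and 0 fell (10 and 0 adjusted over the list alone; median 0.73, adjusted p = 7.9e-05, and adjusted p = 0.391 with an estimated correlation). Nrp1, a coreceptor for vascular endothelial growth factor and semaphorins, rose 16.2-fold (adjusted p = 0.00995). The count was 4 without iPSC replicate 1 or spontaneous replicate 3, 3 without iPSC replicate 2 and 2 without spontaneous replicate 2. Of 19 imprinted genes, 8 rose and 0 fell (8 and 1 adjusted over the list alone; median 0.68, adjusted p = 2.8e-05, and adjusted p = 0.292 with an estimated correlation), including Peg3 (3.56, adjusted p = 0.000683) and the growth factor Igf2 (2.68, adjusted p = 0.00132). The imprinted count was 5 higher and 0 lower without iPSC replicate 1 or spontaneous replicate 2 or 3, and 5 higher and 1 lower without iPSC replicate 2.

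Other lists fell. Of 27 genes of core and naive pluripotency, 15 fell, 0 rose and 12 did not pass (0 higher and 19 lower adjusted over the list alone), with a median of -1.41 and an adjusted p = 1.14e-11. The adjusted p = 0.292 with an estimated correlation, and the count was 9 without iPSC replicate 2 or spontaneous replicate 2. Fbxo15, an Oct4 target gene, fell by 3.23 (adjusted p = 0.00647), while Tdgf1, a coreceptor of Nodal, differed by -0.46 (adjusted p = 0.366) and Dppa5a by -1.26 (adjusted p = 0.0703). Of 23 immediate early and dissociation stress genes, 7 fell and 0 rose (0 higher and 10 lower adjusted over the list alone; median -0.99, adjusted p = 2.59e-08, and adjusted p = 0.292 with an estimated correlation). The AP-1 subunit genes Fosb and Fos fell (-2.72 and -2.36, adjusted p = 0.000431 and 0.000428), and Socs3, a feedback inhibitor of cytokine signalling, fell by 2.01 (adjusted p = 0.000664). Of 14 germ cell genes, 5 fell and 0 rose (0 higher and 6 lower adjusted over the list alone; median -0.91, adjusted p = 1.25e-05, and adjusted p = 0.391 with an estimated correlation), among them Dazl, an RNA-binding protein gene of germ cells (-2.72, adjusted p = 0.00074), and Tex14 (-1.68, adjusted p = 0.000517). Of 19 fibroblast and feeder cell genes, 3 fell and 0 rose (0 higher and 3 lower adjusted over the list alone; median -0.37, adjusted p = 0.000856, and adjusted p = 0.391 with an estimated correlation); the proteoglycan gene Dcn fell by 2.06 (adjusted p = 0.00138). The fibroblast count was 1 without iPSC replicate 1 or spontaneous replicate 2. In the DNA methylation list 4 of 11 fell and 0 rose (1 higher and 4 lower adjusted over the list alone; 1 rose without iPSC replicate 3), with a median of 0.07, which turned negative under 2 of the 3 other scalings, a mean of -0.53 and a camera direction of down (adjusted p = 0.424). The 5-methylcytosine oxidases Tet2 and Tet1 fell (-2.44 and -1.70, adjusted p = 0.000518 and 0.00484).

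Of the 11 lysophospholipid receptors, 2 rose in spontaneous cells and 0 fell, as also when adjusted over the list alone. The risen genes were Lpar4 and Lpar6, a further receptor for lysophosphatidic acid (1.36 ± 0.27 SE, 2.56-fold, adjusted p = 0.00923). Lpar1 differed by 0.37 (adjusted p = 0.121) and the sphingosine 1-phosphate receptor gene S1pr2 by -0.04. The list had a median of 0.10 and a mean of 0.44 (camera adjusted p = 0.0487, and adjusted p = 0.324 with an estimated correlation). The camera call was lost without iPSC replicate 1 (0.0584), iPSC replicate 3 (0.0754), spontaneous replicate 1 (0.0761) or spontaneous replicate 2 (0.0573).

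Across 19938 genes, limma called 397 higher and 314 lower in spontaneous cells than at day 0, and 430 in all without spontaneous replicate 2. Of the 44 lists, 21 passed camera with the preset correlation and 0 with an estimated correlation, where 6 had an unadjusted p under 0.05, and 8 passed fry. Of the lists not given above, 19 genes of epithelial to mesenchymal transition and 17 mesenchymal genes each had 4 higher and 0 lower, also adjusted over the list alone (medians 0.42 and 0.48, adjusted p = 0.000892 and 0.0008). Each count was 1 without iPSC replicate 1, iPSC replicate 2 or spontaneous replicate 3 and 0 without spontaneous replicate 2. The 16 cholesterol synthesis genes shifted up (median 0.35, adjusted p = 0.00333) with 0 called, 1 adjusted over the list alone and 1 without spontaneous replicate 1. Of 19 hypoxia genes 1 fell, also adjusted over the list alone (median -0.38, adjusted p = 0.026), and 0 without spontaneous replicate 2 or 3. The hypoxia call was lost without iPSC replicate 1 (0.262) or spontaneous replicate 3 (0.114). Of 24 surface antigens used to isolate progenitors, 4 rose and 4 fell, also adjusted over the list alone, and 2 rose and 3 fell without spontaneous replicate 2. Their median was -0.08, positive under 1 of the 3 other scalings, the mean was 0.28 and the camera direction was down (adjusted p = 0.836).

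Cardiac cultures were compared with day 0 to see what the optimized protocol changed over the same time. Ttr, which encodes the thyroxine carrier transthyretin, rose from 5.79 ± 0.25 to 10.31 ± 0.92 (23-fold, log2 difference 4.52 ± 0.59 SE, adjusted p = 0.00115). Apob, the main apolipoprotein of low-density lipoprotein, rose 14.3-fold (3.84 ± 0.59 SE, adjusted p = 0.00262) from a dim 5.42 at day 0, so that this fold too may be understated. Cyp26a1 rose 20.2-fold (adjusted p = 0.000725), Fgf5 13.1-fold (adjusted p = 0.000431) and Eomes 11.5-fold (3.53 ± 0.66 SE, adjusted p = 0.00869). Amot, which encodes the Hippo pathway regulator angiomotin, rose 13.4-fold (adjusted p = 0.000523). Fosb fell by 2.81 (adjusted p = 0.000468) and Tcl1 fell by 2.57 (adjusted p = 0.00136). Emp1, an epithelial membrane protein gene, fell by 2.55 (adjusted p = 0.000431).

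The list of extraembryonic visceral and primitive endoderm stood out in cardiac cultures: 8 of 22 genes rose and 0 fell (11 and 0 adjusted over the list alone), with a median of 1.05 and an adjusted p = 1.11e-08 (adjusted p = 0.468 with an estimated correlation). Ttr and Apob belonged to it, as did the trypsin inhibitor gene Spink1 (2.13, adjusted p = 0.00168), whereas Apoe differed by 0.40 (adjusted p = 0.397). The count was 5 without iPSC replicate 1. Both Ttr and Apob were highest in cardiac replicate 1 (11.34 and 10.61, against 9.56 and 8.43 in replicate 2 and 10.04 and 8.75 in replicate 3), the array with Kdr near its day 0 level. The 15 definitive endoderm genes, Ttr among them, gave 3 higher and 0 lower (4 and 0 adjusted over the list alone; median 0.71, adjusted p = 1.92e-05, and adjusted p = 0.0702 with an estimated correlation), with 1 higher without iPSC replicate 1 or 3. Of 18 formative and primed epiblast genes, 7 rose and 1 fell (10 and 1 adjusted over the list alone; median 1.56, adjusted p = 0.000135, and adjusted p = 0.321 with an estimated correlation); Fgf5 and the receptor tyrosine kinase gene Epha1 (2.27, adjusted p = 0.00439) were among those that rose. The member that fell was no longer called without iPSC replicate 3, cardiac replicate 2 or cardiac replicate 3, which left 5 higher and 0 lower. Of 24 surface ectoderm and epithelium genes, 6 rose and 0 fell (7 and 0 adjusted over the list alone; median 0.42, adjusted p = 0.0002, and adjusted p = 0.617 with an estimated correlation), including the small GTPase gene Rab25 (1.90, adjusted p = 0.00334) and the splicing regulator Esrp1 (1.88, adjusted p = 0.00745). The epithelial count was 3 without iPSC replicate 2.

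Mesodermal lists had few called members in cardiac cultures, and their counts moved with cardiac replicate 1. Of 19 primitive streak genes, 3 rose and 0 fell (5 and 0 adjusted over the list alone; median 1.08, adjusted p = 0.000136, and adjusted p = 0.617 with an estimated correlation). Without cardiac replicate 1 the count was 7, and without iPSC replicate 1, iPSC replicate 3, cardiac replicate 2 or cardiac replicate 3 it was 1. Of 19 lateral plate and cardiogenic genes, 2 rose and 0 fell (2 and 0 adjusted over the list alone; median 0.84, adjusted p = 0.00322, and adjusted p = 0.736 with an estimated correlation). That count was 5 without cardiac replicate 1, 1 without iPSC replicate 2, and 0 without iPSC replicate 1, iPSC replicate 3 or cardiac replicate 2, and without the last of these the camera call was lost as well (0.0919). Of 22 cardiac progenitor genes, 3 rose and 0 fell (4 and 0 adjusted over the list alone; median 0.09, adjusted p = 0.159); the count was 1 without iPSC replicate 2 and 0 without iPSC replicate 1, iPSC replicate 3 or cardiac replicate 2, and the list passed camera without cardiac replicate 1 (0.047). Gata6 differed by 0.52 (adjusted p = 0.335). Of the 27 vasculogenic and migration genes, 2 rose and 0 fell (7 and 0 adjusted over the list alone; median 0.40, adjusted p = 0.00079, and adjusted p = 0.604 with an estimated correlation), including Flt1, a receptor for vascular endothelial growth factor (1.75, adjusted p = 0.00223). The count was 7 without cardiac replicate 1 and 1 without iPSC replicate 2, iPSC replicate 3 or cardiac replicate 2.

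Pluripotency genes fell in cardiac cultures, with 13 of 27 lower and 0 higher (0 higher and 14 lower adjusted over the list alone; median -1.25, adjusted p = 4.51e-10, and adjusted p = 0.321 with an estimated correlation). The count was 7 without iPSC replicate 1, 5 without iPSC replicate 2 or cardiac replicate 2, and 8 without cardiac replicate 3. Esrrb, an orphan nuclear receptor gene of the naive state, fell by 2.54 (adjusted p = 0.00564), while Tdgf1 differed by -0.41 (adjusted p = 0.398) and Dppa5a by -1.15 (adjusted p = 0.116), or by -1.48 without cardiac replicate 1 (adjusted p = 0.0469). Of 23 immediate early genes, 5 fell and 0 rose (0 higher and 7 lower adjusted over the list alone; median -0.53, adjusted p = 1.52e-05, and adjusted p = 0.466 with an estimated correlation); Fos fell by 2.14 (adjusted p = 0.000431) and the transcription factor gene Egr1 fell by 1.54 (adjusted p = 0.00139). Of 19 fibroblast genes, 3 fell and 0 rose (0 higher and 3 lower adjusted over the list alone; median -0.60, adjusted p = 1.61e-06, and adjusted p = 0.377 with an estimated correlation), among them Dcn (-1.79, adjusted p = 0.00391) and the collagen gene Col1a2 (-1.23, adjusted p = 0.00825). Of the 11 lysophospholipid receptors, Lpar4 and Lpar6 rose and 0 fell, also when adjusted over the list alone (median 0.04, adjusted p = 0.399). The Lpar6 difference was 1.27 (adjusted p = 0.0172), a call that was lost without iPSC replicate 1, 2 or 3 or cardiac replicate 2 or 3, leaving a count of 1 each time.

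Limma called 251 genes higher and 188 lower in cardiac cultures than at day 0, 284 in all without iPSC replicate 1. Camera passed 14 of 44 lists with the preset correlation and 0 with an estimated correlation, where 5 had an unadjusted p under 0.05, and 6 passed fry. Of the lists not given above, 14 germ cell genes had 3 lower and 0 higher (0 higher and 4 lower adjusted over the list alone; median -0.61, adjusted p = 0.00135), with 5 lower without iPSC replicate 3 and 6 without cardiac replicate 1. Of 30 WNT genes, 1 rose and 0 fell, also adjusted over the list alone (median 0.62, adjusted p = 0.000424). That count was 0 without iPSC replicate 1, iPSC replicate 2 or cardiac replicate 2 and 8 without cardiac replicate 1. Of 19 imprinted genes, 3 rose and 0 fell (6 and 1 adjusted over the list alone; median 0.43, adjusted p = 0.00026), and 3 rose and 1 fell without iPSC replicate 2. Of 24 neuroectoderm genes, 2 rose and 1 fell, also adjusted over the list alone (median -0.23, adjusted p = 0.0433). These counts were 1 and 2 without iPSC replicate 1, 0 and 2 without iPSC replicate 3 or cardiac replicate 3, 2 and 2 without cardiac replicate 1, and 0 and 0 without cardiac replicate 2. The neuroectoderm call was lost without iPSC replicate 3 (0.0943) or cardiac replicate 2 (0.31). In the DNA methylation list 1 rose and 3 fell (1 and 4 adjusted over the list alone; 0 and 2 without iPSC replicate 1). Its median of -0.03 turned positive under 1 of the 3 other scalings and without cardiac replicate 1 (adjusted p = 0.769).

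The libraries labelled sorted were compared with day 0 to see which genes marked FLK1 and PDGFRα positive progenitors. A limit is that the libraries labelled sorted CPC replicates 2 and 3 had Kdr and Pdgfra near or below their day 0 levels. Fits without both leave 1 sorted library, which was assumed to vary like the other groups. It was kept for its high Kdr and Pdgfra, so its mesodermal and cardiac values may follow from that choice. Counts and p-values of such fits, here and below, do not describe sorted progenitors as a group. Fgf5 rose from 5.6 ± 0.28 to 9.81 ± 0.44 (18.4-fold, log2 difference 4.20 ± 0.36 SE, adjusted p = 0.000168). Eomes rose 13-fold (3.70 ± 0.66 SE, adjusted p = 0.00658), with an SD of 1.46 between the sorted libraries. Cyp26a1 rose 11.4-fold (adjusted p = 0.00203) and Has2 7.11-fold (adjusted p = 0.00546). Zfp42 fell from 9.46 ± 0.21 to 5.95 ± 1.57 (adjusted p = 0.00398), Esrrb fell by 2.91 (adjusted p = 0.00278) and Cdyl2, a chromodomain protein gene, fell by 2.98 (adjusted p = 0.000168). Ptgs2, which encodes cyclooxygenase 2, fell by 2.82 (adjusted p = 0.00145).

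Of the 27 pluripotency genes, 14 fell in the libraries labelled sorted and 0 rose (0 higher and 18 lower adjusted over the list alone; median -1.33, adjusted p = 6.69e-16, and adjusted p = 0.364 with an estimated correlation), whereas Tdgf1 differed by -0.03 (adjusted p = 0.968). Of 18 formative and primed epiblast genes, 6 rose and 1 fell (10 and 1 adjusted over the list alone; median 1.48, adjusted p = 3.86e-05, and adjusted p = 0.364 with an estimated correlation), including Epha1 (6.04-fold, adjusted p = 0.00226) and the zinc finger gene Zic2 (2.25, adjusted p = 0.0102). Without iPSC replicate 2 the counts were 4 and 0, without iPSC replicate 3 they were 6 and 0, and without sorted CPC replicate 1 they were 7 and 0. Of 19 primitive streak genes, 2 rose and 0 fell (7 and 0 adjusted over the list alone; median 1.02, adjusted p = 3.69e-06, and adjusted p = 0.527 with an estimated correlation), with Fgf8 higher by 2.01 (adjusted p = 0.0082). The streak count was 9 without sorted CPC replicate 3. Of 24 epithelial genes, 5 rose and 0 fell (6 and 0 adjusted over the list alone; median 0.37, adjusted p = 0.00123, and adjusted p = 0.685 with an estimated correlation), among them Esrp1 (1.97, adjusted p = 0.0056) and the desmosome gene Dsp (1.72, adjusted p = 0.00184). Without sorted CPC replicates 2 and 3 the Esrp1 call was lost (0.0865). The epithelial count was 2 without iPSC replicate 1, 2 or 3, 8 without sorted CPC replicate 1 and 3 without sorted CPC replicate 2 or 3. The call of the list was lost without sorted CPC replicate 3 (0.22), and without replicates 2 and 3 of the sorted group 1 member was higher and 3 were lower.

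Lists named for the heart lineage had few called members in the sorted group. Of 22 cardiac progenitor genes, 1 rose and 0 fell (1 and 0 adjusted over the list alone, with a median of 0.04 and a camera adjusted p = 0.378). Gata4, a zinc finger factor of the heart, differed by 0.52 (adjusted p = 0.3), or by 1.24 without sorted CPC replicates 2 and 3. The count was 2 without sorted CPC replicate 3, and the list passed camera without sorted CPC replicate 2 (0.0282). Of 19 lateral plate genes, 0 were called by limma (median 0.40, adjusted p = 0.54). Of 14 germ cell genes, 6 fell and 0 rose (0 higher and 6 lower adjusted over the list alone; median -0.71, adjusted p = 5.18e-05, and adjusted p = 0.546 with an estimated correlation), including Dazl (-2.50, adjusted p = 0.00151), and 2 fell without iPSC replicate 1. Of 19 fibroblast genes, 2 fell and 0 rose (0 higher and 2 lower adjusted over the list alone; median -0.36, adjusted p = 4.79e-05, and adjusted p = 0.527 with an estimated correlation); Dcn fell by 2.17 (adjusted p = 0.00143), and 1 fell without iPSC replicate 1, iPSC replicate 3 or sorted CPC replicate 2. Of 23 immediate early genes, 2 fell and 0 rose (0 higher and 2 lower adjusted over the list alone; median -0.11, adjusted p = 0.0469, and adjusted p = 0.72 with an estimated correlation), among them Socs3 (-1.56, adjusted p = 0.00278). The immediate early count was 1 without iPSC replicate 1 or 2, and the call of the list was lost without iPSC replicate 1 (0.0661), iPSC replicate 2 (0.0874) or sorted CPC replicate 1 (0.964). Of 26 genes of G2/M and mitosis, 0 were called by limma, but the list shifted down (median -0.23, adjusted p = 4.79e-05, and adjusted p = 0.576 with an estimated correlation); Ccnb2, a mitotic cyclin gene, differed by -0.42 (adjusted p = 0.0351) and the topoisomerase gene Top2a by -0.17 (adjusted p = 0.467). Of the 11 lysophospholipid receptors, Lpar4 and Lpar6 (1.43, adjusted p = 0.00972) rose and 0 fell, also when adjusted over the list alone (median 0.04, adjusted p = 0.52).

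Limma called 157 genes higher and 263 lower in the sorted group than at day 0. Camera passed 15 of 44 lists with the preset correlation and 0 with an estimated correlation, where 3 had an unadjusted p under 0.05, and 2 passed fry. Of the lists not given above, 30 WNT genes had 1 higher and 0 lower (3 and 0 adjusted over the list alone; median 0.43, adjusted p = 0.000656). The WNT counts were 2 and 0 without sorted CPC replicate 1, 1 and 1 without replicate 2, 8 and 0 without replicate 3, and 5 and 0 without replicates 2 and 3. Of 26 extracellular matrix genes, 1 rose and 2 fell (1 and 3 adjusted over the list alone; median -0.35, adjusted p = 0.00823), with the call lost without sorted CPC replicate 2 (0.083). Of 19 imprinted genes, 2 rose and 1 fell (3 and 1 adjusted over the list alone; median 0.23, adjusted p = 0.0336), and 2 and 0 without iPSC replicate 1 or 3 or sorted CPC replicates 2 and 3. The imprinted call was lost without sorted CPC replicate 1 (0.0961) or 3 (0.0996). Of 27 vasculogenic and migration genes, 2 rose and 0 fell, also adjusted over the list alone (median 0.40, adjusted p = 0.0426). These counts were 1 and 0 without iPSC replicate 1 or 3, 4 and 0 without sorted CPC replicate 3, and 7 and 1 without sorted CPC replicates 2 and 3. The vasculogenic call was lost without iPSC replicate 2 (0.0867), sorted CPC replicate 1 (0.158) or sorted CPC replicate 2 (0.093). Of 19 hypoxia genes 0 rose and 1 fell, also adjusted over the list alone (median -0.30, adjusted p = 0.0128). The hypoxia counts were 0 and 0 without iPSC replicate 1 or sorted CPC replicate 1, 1 and 2 without sorted CPC replicate 2, and 0 and 2 without sorted CPC replicates 2 and 3. The hypoxia call was lost without iPSC replicate 1 (0.226) or sorted CPC replicate 3 (0.108). In the DNA methylation list 0 rose and 3 fell (1 and 4 adjusted over the list alone; median -0.13, adjusted p = 0.0469), and 1 rose and 3 fell without iPSC replicate 3 or sorted CPC replicate 3. Its call was lost without iPSC replicate 2 (0.0837), iPSC replicate 3 (0.145) or sorted CPC replicate 3 (0.327), and its median was 0.03 without sorted CPC replicates 2 and 3. The 23 oxidative phosphorylation genes, of which 0 were called, shifted down (median -0.17, adjusted p = 0.0128), with the call lost without iPSC replicate 3 (0.121), sorted CPC replicate 1 (0.0813) or sorted CPC replicate 3 (0.138).

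The 3 day 4 groups shared many changed genes, all measured against the same 3 day 0 arrays. Of 878 genes called in at least 1 comparison with day 0, 105 were higher and 152 lower in all 3, and 0 genes were called in opposite directions in any pair of groups. The genes in all 3 numbered 257, against 163 without cardiac replicate 2 and 168 without iPSC replicate 1. Among the named genes, Lpar4, Eomes, Fgf5, Cyp26a1 and Has2 rose in each group, and Tcl1, Esrrb, Cdyl2, Emp1, Dazl and Dcn fell in each. Spontaneous and cardiac cells shared 166 higher and 179 lower genes, where independent lists of these sizes would share 5 and 2.96. Spontaneous and sorted cells shared 123 and 209 (independent 3.13 and 4.14), and cardiac and sorted cells shared 118 and 154 (independent 1.98 and 2.48). The correlation of the differences across genes was 0.888, 0.822 and 0.787 for the same pairs, against 0.411, 0.372 and 0.266 in simulated unchanged groups that shared simulated day 0 arrays. The covariance was 0.163, 0.145 and 0.125 against 0.01 in each. The simulated noise was independent between genes, so joint deviations of the measured day 0 arrays were not covered. The 3 control arrays cannot be divided into separate sets, so part of the excess may come from the shared controls, and genes are not independent replicates.

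**Figure D2:**
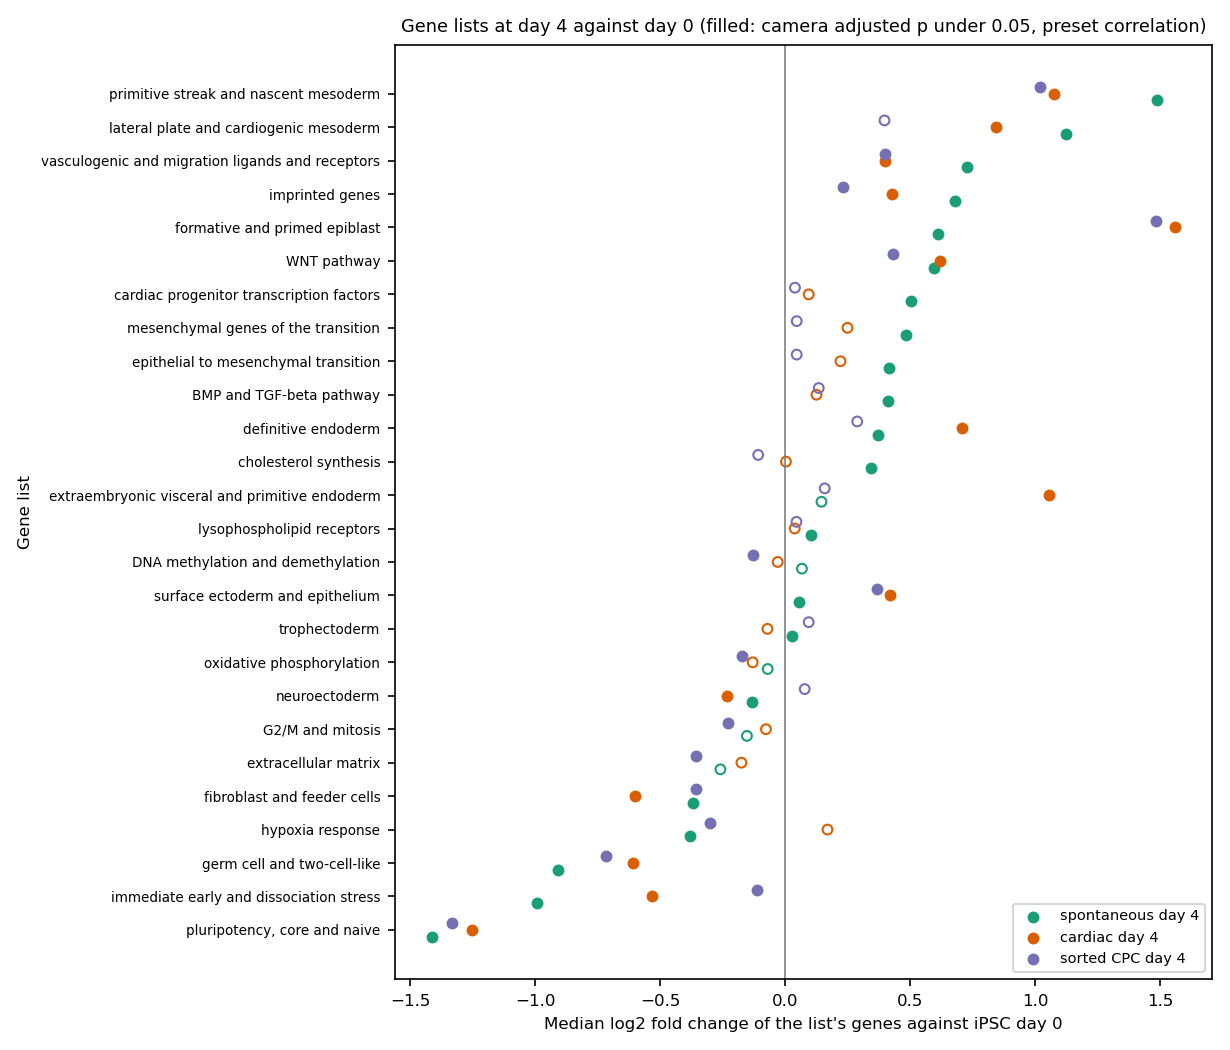
Median log2 fold change against day 0 of 26 gene lists (x axis) in spontaneous, cardiac and sorted day 4 groups; filled symbols passed camera with the preset correlation. Pluripotency medians were -1.41, -1.25 and -1.33 and the visceral endoderm median was 1.05 in cardiac cultures, while the DNA methylation medians of spontaneous and cardiac cells changed sign under other scalings.

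Cardiac and spontaneous cultures were compared to ask what the cardiac protocol changed at day 4. No single gene passed: limma called 0 of 19938, with 743 at an unadjusted p under 0.05 and a smallest adjusted p of 0.762; without spontaneous replicate 1 the count was 1. Of the 44 lists, 19 passed camera with the preset correlation, but 0 passed with an estimated correlation or by fry, and 0 members of the lists given here were called. The 19 hypoxia response genes were higher in cardiac cultures (median 0.76, adjusted p = 2.07e-15, and adjusted p = 0.247 with an estimated correlation), as were the 16 glycolysis genes (median 0.40, adjusted p = 3.91e-11, and adjusted p = 0.247 with an estimated correlation). The glucose transporter genes Slc2a1 and Slc2a3 differed by 0.45 and 0.41 (adjusted p = 0.999 each), or by 0.32 and 0.25 without cardiac replicate 1. The 22 visceral endoderm genes were higher by a median of 0.41 (adjusted p = 2.88e-15, and adjusted p = 0.247 with an estimated correlation), with 7 called higher and 0 lower adjusted over the list alone. Without cardiac replicate 1, the array with low Kdr, the medians were 0.43 for hypoxia, 0.28 for glycolysis and 0.05 for visceral endoderm. Over all arrays Ttr and Apob differed by 2.61 and 2.80 (limma adjusted p = 0.999 each). In both genes cardiac replicates 2 and 3 also exceeded all spontaneous arrays. The 16 cholesterol synthesis genes were lower (median -0.37, adjusted p = 2.46e-06, and adjusted p = 0.389 with an estimated correlation), with Hmgcs1, the synthase that makes HMG-CoA, at -0.53 (adjusted p = 0.999). The 19 lateral plate genes were lower by a median of -0.45 (adjusted p = 4.05e-05, and adjusted p = 0.389 with an estimated correlation), or -0.14 without cardiac replicate 1. Over the 314 genes that fell in spontaneous cells, the share of day 0 signal was 0.344 in cardiac replicate 1, the largest of the day 4 libraries, beside 0 and 0.083 in cardiac replicates 2 and 3. The 22 cardiac progenitor genes had a median of -0.16 (adjusted p = 0.00024, and adjusted p = 0.389 with an estimated correlation), with Gata4 at -0.05. The 17 mesenchymal genes, such as the fibronectin gene Fn1 (-0.64, adjusted p = 0.999), had a median of -0.56 (adjusted p = 1.66e-06, and adjusted p = 0.247 with an estimated correlation). Without cardiac replicate 1 Fn1 differed by -0.17 and the median was -0.20. The medians were then -0.37 for cholesterol synthesis and -0.15 for cardiac progenitor genes, and Gata4 differed by -0.14. Cardiac replicate 1 was singled out for its Kdr value. Replicate 2 deviated no less from the group mean (root mean square 0.26, against 0.238 and 0.156 in replicates 1 and 3). Medians without replicate 2 are not given here, so replicate 1 is not shown to be the only array that moved these lists.

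Further lists differed between cardiac and spontaneous cultures by smaller medians. Higher were the lists of formative epiblast (0.33, adjusted p = 0.000322), germ cells (0.24, adjusted p = 0.00336, 1 member higher adjusted over the list alone), surface ectoderm (0.20, adjusted p = 0.00936) and immediate early genes (0.16, adjusted p = 0.00705). Lower were those of epithelial to mesenchymal transition (-0.52, adjusted p = 1.84e-05), BMP and TGF-beta (-0.25, adjusted p = 2e-05), neural crest (-0.24, adjusted p = 0.0016) and WNT (-0.23, adjusted p = 0.00407). Trophectoderm (-0.18, adjusted p = 0.0056), fibroblast (-0.17, adjusted p = 0.00691), sarcomere (-0.11, adjusted p = 0.00336) and HOX genes (-0.10, adjusted p = 0.0102) were lower too. The germ cell, surface ectoderm and WNT calls were lost without cardiac replicate 1 (0.501, 0.112 and 0.423). Medians without that array were -0.17 for epithelial to mesenchymal transition, -0.14 for BMP and TGF-beta, -0.12 for neural crest and 0.29 for epiblast. The sarcomere, fibroblast, trophectoderm and HOX calls were lost without cardiac replicate 2 (0.332, 0.265, 0.0507 and 0.68), the surface ectoderm call also without cardiac replicate 3 (0.0995) and the immediate early call without spontaneous replicate 1 (0.175). Pluripotency genes did not pass (median 0.11, adjusted p = 0.0711), except without spontaneous replicate 3 (0.00238) or cardiac replicate 2 (0.00967), and their median was -0.03 without cardiac replicate 1.

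Sorted libraries were compared with unsorted cardiac cultures to ask what the FLK1 and PDGFRα gate enriched. The limma count was 0, with 3135 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.117; it was 1 without sorted CPC replicate 3. Without the libraries labelled sorted CPC replicates 2 and 3, it was 98, with 4 higher and 94 lower in the remaining sorted library. The 22 visceral endoderm genes were lower in the sorted libraries by a median of -0.92 (adjusted p = 3.37e-11, and adjusted p = 0.826 with an estimated correlation), with 0 higher and 11 lower adjusted over the list alone. Ttr differed by -2.33 ± 0.59 (SE, adjusted p = 0.265) and Apoe by -0.62 (adjusted p = 0.302). Without cardiac replicate 1 the median was -0.58 and these genes differed by -1.82 and -0.29. The median was -1.24 and they differed by -2.57 and -1.22 without sorted CPC replicates 2 and 3. The hypoxia list was lower by a median of -0.72 (adjusted p = 2.15e-07, and adjusted p = 0.826 with an estimated correlation) and the glycolysis list by -0.27 (adjusted p = 0.000835, and adjusted p = 0.919 with an estimated correlation), or by -0.43 and -0.15 without sorted CPC replicates 2 and 3. The immediate early list was higher (median 0.25, adjusted p = 0.000793, and adjusted p = 0.919 with an estimated correlation), with 5 higher and 0 lower adjusted over the list alone; without sorted CPC replicates 2 and 3 its median was -0.11, and without replicate 3 alone 1 member was called. Cardiac progenitor genes had a median of -0.05 (adjusted p = 0.56), with Gata4 at -0.70 (adjusted p = 0.285). The median was 0.18 and Gata4 differed by 0.03 without sorted CPC replicates 2 and 3, the libraries low in Kdr. That list passed camera without sorted CPC replicate 1 (0.0288). Of the 44 lists, 9 passed camera with the preset correlation, 0 with an estimated correlation and 0 by fry.

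Other lists moved less between sorted and cardiac libraries. Definitive endoderm (median -0.40, adjusted p = 0.00336, 2 members lower adjusted over the list alone), lateral plate (-0.30, adjusted p = 0.0111), DNA methylation (-0.29, adjusted p = 0.0494) and G2/M genes (-0.13, adjusted p = 0.00336) were lower, and sarcomere genes were higher (0.20, adjusted p = 0.0278). The lateral plate call was lost without cardiac replicate 2 (0.278), sorted CPC replicate 2 (0.343) or sorted CPC replicate 3 (0.066). Its median was -0.61 without cardiac replicate 1 and changed sign to 0.13 without sorted CPC replicates 2 and 3. The DNA methylation call was lost without cardiac replicate 1 (0.187), cardiac replicate 2 (0.0544) or sorted CPC replicate 3 (0.316), and the G2/M call without cardiac replicate 2 (0.237). The sarcomere call was lost without cardiac replicate 2 (0.218), sorted CPC replicate 1 (0.0552) or sorted CPC replicate 3 (0.278). Pluripotency genes did not pass (median -0.12, adjusted p = 0.178), except without cardiac replicate 2 (0.00418) or sorted CPC replicate 2 (0.00255), and 4 were lower without sorted CPC replicates 2 and 3 (median -0.65). Fibroblast genes did not pass either (0.20, adjusted p = 0.227).

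Sorted libraries were also compared with spontaneous cells, and 1 gene passed. Fos was 8.52 ± 0.28 in the libraries labelled sorted and 6.73 ± 0.33 in spontaneous cells, a log2 difference of 1.78 ± 0.21 (SE, 3.44-fold, adjusted p = 0.028), with all 3 sorted above all 3 spontaneous arrays. The Fos call was lost without spontaneous replicate 3 (adjusted p = 0.203), sorted CPC replicate 1 (0.0572) or sorted CPC replicate 2 (0.0871). For Fos, sorted CPC day 4 vs spontaneous day 4, the call was also lost with array weights (adjusted p = 0.0618), median centring (0.0793), a fit of only the 6 arrays compared (0.136) and treat. Of the 44 lists, 15 passed camera with the preset correlation, 0 with an estimated correlation and 0 by fry. The 23 immediate early genes were higher as a list (median 0.55, adjusted p = 2.19e-08, and adjusted p = 0.404 with an estimated correlation), with 6 higher and 0 lower adjusted over the list alone. Without sorted CPC replicates 2 and 3 their median was 0.08 and the Fos difference was 1.57 (adjusted p = 0.0828). The number of list members called was 0 without spontaneous replicate 3, sorted CPC replicate 1 or sorted CPC replicate 2, and 2 without sorted CPC replicate 3. The 19 lateral plate genes were lower (median -0.75, adjusted p = 2.19e-08, and adjusted p = 0.404 with an estimated correlation), with 0 higher and 6 lower adjusted over the list alone and a median of -0.04 without sorted CPC replicates 2 and 3. The 31 BMP and TGF-beta genes were lower by a median of -0.29 (adjusted p = 0.000125, and adjusted p = 0.404 with an estimated correlation), with 9 lower adjusted over the list alone, and the 16 cholesterol synthesis genes by -0.41 (adjusted p = 6.19e-06, and adjusted p = 0.538 with an estimated correlation). These medians were -0.29 and -0.63 without sorted CPC replicates 2 and 3. Gata4 differed by -0.75 (adjusted p = 0.346), the imprinted gene Peg10 by -1.44 (adjusted p = 0.295) and the chemokine receptor gene Cxcr4 by -1.80 (adjusted p = 0.431). These differences were -0.02, -0.85 and, with the sign changed, 0.37 (adjusted p = 0.861) without the same 2 libraries. The limma count, 1 of 19938 with 2310 at an unadjusted p under 0.05, was 18 without spontaneous replicate 1, 0 without spontaneous replicate 3 or sorted CPC replicate 1, 4 without sorted CPC replicate 3 and 5 without sorted CPC replicates 2 and 3.

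Among further lists, formative epiblast (median 0.46, adjusted p = 0.00566) and neuroectoderm (0.17, adjusted p = 0.0222) were higher in sorted than in spontaneous cells. Mesenchymal genes (-0.70, adjusted p = 5.46e-05), epithelial to mesenchymal transition (-0.58, adjusted p = 0.00021), imprinted genes (-0.35, adjusted p = 0.00306), extracellular matrix (-0.24, adjusted p = 0.00721) and vasculogenic and migration genes (-0.21, adjusted p = 0.0141) were lower. Oxidative phosphorylation (-0.15, adjusted p = 0.00107), cardiac progenitor (-0.13, adjusted p = 0.00245), WNT (-0.13, adjusted p = 0.0414) and G2/M genes (-0.12, adjusted p = 0.033) were lower as well. Adjusted over the list alone, 5 imprinted and 2 cardiac progenitor genes were lower. The epiblast, cardiac progenitor, matrix, WNT, imprinted and vasculogenic calls were lost without sorted CPC replicate 2 (0.293, 0.293, 0.216, 0.101, 0.0968 and 0.0657). The neuroectoderm, WNT, G2/M and vasculogenic calls were lost without sorted CPC replicate 3 (0.197, 0.43, 0.222 and 0.184), the WNT and G2/M calls without spontaneous replicate 1 (0.0564 and 0.101) and the WNT call without spontaneous replicate 2 (0.0698). Of the imprinted genes 2, and of the cardiac progenitor genes 1, were called lower without spontaneous replicate 1. With sorted CPC replicates 2 and 3 both left out, the medians were -0.01 for mesenchymal genes, -0.17 for imprinted genes and 0.15 for epiblast, and those of cardiac progenitor, WNT and vasculogenic genes changed sign (0.08, 0.11 and 0.02). Pluripotency and fibroblast genes did not pass (medians -0.01 and 0.03, adjusted p = 0.72 each), and these medians changed sign under 2 and 3 of the 3 other scalings. The camera direction was down for both. Pluripotency genes passed upward without sorted CPC replicate 1 (0.0112) and downward without sorted CPC replicate 2 (0.0284).

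A moderated F test over the 4 groups passed 1169 of 19938 genes (5.86%), Lpar4 among them (adjusted p = 0.00423). The F count was 354, 360 and 572 without iPSC replicates 1, 2 and 3, 593 and 629 without spontaneous replicates 2 and 3, 1791 without sorted CPC replicate 3 and 2451 without sorted CPC replicates 2 and 3. Genes higher in the sorted group than in each other group numbered 0 by limma, and also 0 at an unadjusted p under 0.05 with a log2 difference of at least 1, so neither Lpar4 nor either gate gene was highest in the libraries labelled sorted by this measure.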

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

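The tests of the 3 patterns weighed here and the counts over other splits of the samples were chosen after the results were seen.

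Fos was higher in the libraries labelled sorted than in spontaneous cells by 1.78 on the log2 scale, a test of the difference between both day 4 groups, but the call was lost with array weights, median centring, a fit of only the 6 arrays and treat, and without each of 3 single arrays. Probe sets with no listed gene, outside the main comparisons, gave 17 calls in spontaneous cells (6 higher and 11 lower), 6 in cardiac cultures (2 and 4) and 18 in the sorted group (2 and 16) against day 0, out of 12147. Probe sets with several listed genes gave 46 calls (5 higher and 41 lower), 37 (5 and 32) and 37 (3 and 34) in the same order, out of 1621.

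In the libraries labelled sorted CPC replicates 2 and 3, Kdr (6.25 and 6.03) lay near its day 0 level although the gate selected its product. Mislabelled day 0 cells are argued against by the 314 genes that fell in spontaneous cells, whose median position, from 0 at day 0 to 1 in spontaneous cells, was 0.74 and 0.883 in these libraries. Dilution with day 0 cells would have to supply 0.977 and 0.986 of the signal to account for Kdr, but those genes gave a day 0 share of at most 0.166; the share was 0.344 in cardiac replicate 1, also low in Kdr, where Kdr would need 1.005, so day 0-like cells in that library stay open but were too small a share for its Kdr. An exchange of labels with cardiac replicates 2 and 3 stays open: grouping sorted CPC replicate 1 with those cardiac arrays, all high in Kdr, called 27 genes against 0 for the labelled groups, whereas 6 of 23 immediate early genes lay above in the labelled sorted group and 0 in the exchanged one (chance 1.15). Both counts rest on groupings looked at after Kdr and Fos were seen, a varying share of Kdr-positive cells would call genes the same way, and no biological explanation was tested.

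Of 23 immediate early genes, only Fos passed between sorted and spontaneous libraries. At an estimated correlation the list failed camera (adjusted p = 0.404). In 10 (Fos, Fosb, Jun, Jund, Egr1, Egr2, Dusp1, Zfp36, Btg2 and Socs3) all 3 sorted lay above all 3 spontaneous libraries, and 1 lay below. Chance gives 1.15 each way (5%), and 9.44% of all genes lay above. The 10 are named after their values were seen. Undifferentiated cells are argued against, since the share of day 0 signal in other genes was at most 0.2 of the share that Fos would need. Handling during the sort may have raised these genes, but sorting and group coincide as labelled, so handling and a state of the progenitors cannot be told apart by the value of 10. Against cardiac cultures 6 members were separated in the same direction.

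Visceral endoderm genes were higher in cardiac cultures, and 8 members were called. Their deviations within groups were correlated over the 9 day 4 libraries (mean pairwise r of 0.814 across libraries, against a median of 0.09 and a 95th percentile of 0.343 in 10000 random sets drawn from 243 called genes), so a varying share of visceral endoderm-like cells between libraries is a candidate explanation. A gate on FLK1 and PDGFRα, absent in the cardiac and spontaneous cultures, applied to 3 of these 9 libraries as labelled, yet in sorted CPC replicate 2 Ttr, Apoa1 and Apob measured 9.48, 8.57 and 7.48. Of the 22 genes measured, 8 belonged also to another list, 15 lay above the table median at day 0 already and 1 of those called stood in another list. Between cardiac and spontaneous cells the list differed by a median of 0.41 (adjusted p = 2.88e-15, and adjusted p = 0.247 with an estimated correlation), but by 0.05 without cardiac replicate 1, the array in which the signals of Apoe, Dab2, Ttr and Apob were 12.32, 11.88, 11.34 and 10.61. That median hides single members. Of the 8 called against day 0, Ttr, Apob, Apoa1, Afp, Spink1 and Rbp4 exceeded all spontaneous arrays in cardiac replicates 2 and 3 too. Dab2 and Cited1 overlapped them. Ttr was 9.56 and 10.04 there, against 8.45, 7.57 and 7.08 in spontaneous replicates 1, 2 and 3.

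Other splits of the samples were counted for each comparison of 3 with 3 arrays, where 10 splits are too few for a share under 0.05. Against day 0 the real splits called 711, 439 and 420 genes and the highest other split 0, so that 1 of 10 reached the real count in each. For cardiac against spontaneous cells the real count was 0 and the highest other 18, and for sorted against cardiac libraries 0 and 27, so all 10 splits trivially reached the real count. The split with 27 is that of Kdr-high against Kdr-low libraries (sorted CPC replicate 1 and cardiac replicates 2 and 3 against the others). Whether the splits with 18 and 27 reflect a structure of the samples other than their groups was not tested. For sorted against spontaneous cells the real count was 1 and the highest other 0, with 1 of 10 reaching it. For the F test over the 4 groups, 1 of 100 regroupings, the real one, gave 1169 genes, and the highest other gave 667. Chance alone is thus unlikely for that count, but 100 regroupings do not exclude it. The calls above were 711, 439 and 420 against day 0, and 0, 0 and 1 between day 4 groups. The F count therefore does not show that the day 4 groups differ from each other.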

How the results depend on the processing

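The fits without sorted CPC replicates 2 and 3, the alternatives of the overlap and the list tests with arrays left out were chosen after seeing the data. Signal over background limits dim genes, although the filter that kept 12340 genes weakened 0 of 352 named-gene results and strengthened 1. Of 359 named-gene results, 0 reversed under any alternative run; treat weakened 146, robust estimation 20, array weights 12, the fit of 6 arrays 8, the replicate block 7, cyclic loess 6, median centring 5, the prior without trend 3, repeated quantile normalization 2 and the mean of probe sets 1. Results not called at first became called in 14 cases with the fit of 6 arrays, 13 with array weights, 6 without a minimum fold change and 2 each with median centring, repeated quantile normalization and cyclic loess. Uncalled differences changed sign in 18, 11, 5, 4 and 1 cases with array weights, median centring, repeated quantile normalization, cyclic loess and the mean of probe sets. Without a replicate the losses were 49, 41 and 30 of 267 for iPSC replicates 1, 2 and 3, 11, 30 and 24 of 176 for spontaneous, 1, 16 and 9 of 142 for cardiac and 3, 4 and 3 of 133 for sorted. Without sorted CPC replicates 2 and 3, 11 were weaker, 12 stronger and 24 changed sign, and 20 changed sign without cardiac replicate 1. Scalings moved the median of all genes by at most 0.083, and median centring took the share of calls that were higher from 55.8% to 63.8% in spontaneous and from 57.2% to 66.8% in cardiac cells.

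Without a minimum fold change, which by construction admits smaller effects, limma called 1943, 1231 and 1019 genes in spontaneous, cardiac and sorted cells against day 0, and 605 in all 3. Treat, which by construction asks more, called 18, 6 and 8, with 2 in all 3 and 0 between sorted and spontaneous cells, where Fos was the gene lost. Array weights gave 4669 genes in the F test, 3 between cardiac and spontaneous cells and 0 between sorted and spontaneous cells; the cause was not tested. Median centring and the fit of only the 6 arrays each gave 0 between sorted and spontaneous cells, cause also not tested. Without sorted CPC replicates 2 and 3, where the lone sorted library was assumed to vary like the other groups, the counts were 824 against day 0, 98 against cardiac, 5 against spontaneous and 2451 in the F test. Of 264 list tests 93 passed, against 0 with an estimated correlation and 16 with fry, all against day 0; fry asks another question.

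Leaving out 1 array gave 430 to 651 genes for spontaneous, 284 to 653 for cardiac and 294 to 608 for sorted cells against day 0. It gave 0 to 1 for cardiac against spontaneous, 0 to 1 for sorted against cardiac, 0 to 18 for sorted against spontaneous, 354 to 1791 for the F test, 0 to 0 for genes highest in sorted cells, 163 to 342 for the overlap and 89 to 105 for list tests. The pluripotency list between sorted and spontaneous cells, down with an adjusted p of 0.72, reversed to up without sorted CPC replicate 1 (0.0112, in a range from 0.0112 to 0.754 with 1 array left out); the cause was not tested. With the replicate number as a block, counts were 688, 435 and 416 against day 0, 0, 0 and 1 between day 4 groups, 1074 in the F test, 250 in the overlap and 93 list tests. Of 18 pairs of like number, 6 correlated over 0.1 (range -0.382 to 0.307). Unlike pairs were not compared, so pairing stays open.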

Other observations

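The test of X dosage was set out before its result was seen, and the test of a chance share of X-linked genes was chosen after.

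X-linked genes were frequent among the genes that rose. Against day 0, 57 of 739 X-linked genes (7.71%) were called higher in spontaneous cells, 39 (5.28%) in cardiac cultures and 28 (3.79%) in the sorted group, beside 339 (1.77%), 210 (1.1%) and 129 (0.68%) of 19103 autosomal genes. Lpar4, Fndc3c1 and Amot were among them. A chance share is argued against by exact Fisher tests, two-sided, with adjusted p of 8.22e-18, 7.8e-14 and 9.7e-12 in this order, although genes are not independent. Genes called lower were not enriched for X linkage (adjusted p = 0.542, 1 and 0.542).

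One hypothesis is a chromosome-wide difference in X dosage between day 0 and day 4 cells. Among the 345 X-linked genes brighter than the table median, the median log2 fold change exceeded that of autosomal genes of the same kind by 0.195 in spontaneous cells, 0.188 in cardiac cultures and 0.138 in the sorted group, and 69.9%, 72.2% and 66.7% of them had a positive difference, against 54.5%, 56% and 49.3% of autosomal genes. All 9 day 4 libraries lay above the day 0 libraries by this measure (0.093 to 0.226, against -0.026 to 0.023). The shift lay between the bound of 0.1 that would have argued against a chromosome-wide difference and the 0.3 that it was predicted to reach, so the question stays open. After the shift was subtracted, 45, 32 and 23 X-linked genes were still called higher (exact Fisher test, p = 1.03e-11, 5.06e-10 and 1.06e-08), so a uniform shift alone did not account for the excess. Xist, the RNA that silences an X chromosome, looked up after the X-linked excess was seen, measured 3.91 to 4.56 on all 12 arrays, below every array median. Other causes of the excess were not tested.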
